A study of Bos taurus with 215 samples.

How the data were processed

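The data are RNA-seq counts per gene for 215 libraries of bovine endometrium and conceptus. Per the labels' protocols, tissue was ground, RNA was extracted with Trizol, and libraries were made with a strand-specific kit for polyadenylated RNA. The submitters' processing notes name HISAT2 2.2.1, SAMtools 1.10, featureCounts 2.0.1 and the genome build ARS-UCD1.2. The authors deposited whole-number counts for 27607 Ensembl gene identifiers, not normalized, and 26929 of these had at least 1 count. The strand setting of the counting is not given in the sources used here, so overlapping genes and near-identical gene copies may share counts. Counts come from reads without molecular identifiers, so counting precision is a best case. Depth ranged from 2 counts to 33.1 M counts per library, where M stands for 1000000.

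The table gives identifiers only and the files do not pair them with gene symbols. Of the 27607 identifiers, 0 matched the table of gene names at hand. The tests of named gene lists fixed in advance, the relation of interferon tau to the interferon response, the XIST covariate and the rule for naming genes by symbol could therefore not be run. Under that rule the text would have named the called genes with a mean of at least 5 CPM and the largest fold changes in either direction. The same order was kept for identifiers, with at most 2 per direction and comparison, except that all 6 genes with an interaction of treatment and day are named, some with under 5 CPM, a choice made after their values were seen.

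The labels give tissue, day, treatment and gestation number. Libraries of one gestation and tissue were added up before testing, because they are not independent replicates, and p-values refer to the spread between gestations. A sum had to reach 100000 counts, a limit set after the totals were seen. It left out the ET extra-embryonic tissue of gestation 8, whose library held 61 counts. Number 168 occurred only for extra-embryonic tissue and number 169 only for endometrium, both of ET on day 18. Whether they are the same gestation is not known, and they were not paired. Counts of gestations over several tissues are therefore counts of gestation numbers. Libraries of the same gestation and tissue were compared for duplicates. Among 192 pairs the lowest chi-square per degree of freedom was 6.19, 0 columns were identical, and no library was merged as a duplicate. Caruncular and intercaruncular tissue come from the same gestations according to the labels, so comparisons between them used the gestation as a block.

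All choices in this paragraph were made before the data were examined. Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test, with TMM factors and filterByExpr at its defaults (minimum count 10, minimum total 15). Genes with a Benjamini-Hochberg adjusted p below 0.05 were called. ET was compared with AI in each of the 6 tissues and days, day 25 with day 18 and the treatment by day interaction in each endometrial part, and caruncular with intercaruncular tissue and the treatment by region interaction on each day. The standard error of a log2 fold change was its size divided by the square root of the F statistic. CPM are counts per M of the summed library with the TMM factor. The alternatives were size factors of the DESeq2 type in edgeR, no low-count filter, DESeq2 1.42.0, limma 3.58.1 on single libraries with duplicateCorrelation, each gestation left out in turn, gestation numbers below 100 only (the 7 gestations numbered 100 or more are all ET), gestation 162 left out (it had 16 libraries, and the labels do not say whether all come from 1 animal), all groups of a region in one fit, and no gestation block. Agreement of ET effects between the 2 endometrial parts was a Pearson r over genes with 100 permutations of labels over gestations, also with genes of at least 5 CPM. Co-expression used log2(CPM + 1), 1000 genes per tissue, an absolute r of at least 0.9 (0.95, or Spearman's rho, as alternatives) and 100 re-pairings, with the larger group resampled to the smaller.

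The following were chosen after seeing the data. Gene groups were taken from the other day, which was studied in different animals. Caruncle-high and intercaruncle-high genes differed at least 2-fold between the parts with an adjusted p below 0.05. Conceptus-high and endometrium-high genes differed by at least 3 in log2(CPM + 1) from both endometrial parts or from the conceptus. Conceptus-only genes had at least 50 CPM in the conceptus and under 1 CPM in both parts, and endometrium-only genes the reverse. The first 4 groups were tested by camera with a preset correlation of 0.01, by camera with an estimated correlation and by fry, adjusted over 24 tests. Other additions were fits without libraries under 1 M counts, with sums thinned to the smallest sum, with log10 of the sum as a covariate, and without a library high in genes that were conceptus-only on the other day. Agreement was also computed between the days for each part and between extra-embryonic tissue and chorion, and the covariance was counted beside r. Permuted r was counted by its size in either direction, and permuted covariance in the positive direction only. An axis was computed as the first principal component of log2 CPM between libraries of the same gestation and part, after the mean of each gestation and part was removed. Its sign was set so that the score rose with the library's total. Each gestation was scored on the axis of the other day. Whole profiles were compared by root mean square distance to the mean of either treatment, with the gestation itself left out, exactly over all splits.

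The edgeR test was tested on simulated data with the real genes, depths and dispersions, in which 100 genes changed 2-fold and 100 changed 4-fold. The simulated genes varied independently of each other, while real genes can vary together, so the shares below hold for independent genes only. Of 2-fold changes it recovered 50% and 56%, and of 4-fold changes 88% and 93%, in caruncular and intercaruncular endometrium on day 25. In extra-embryonic tissue it recovered 39% and 84%. The share of false calls among all calls was between 2.4% and 8.33% over the 6 comparisons.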

Results

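RNA was sequenced from the uterine lining and the conceptus of cattle pregnancies that began either with artificial insemination (AI) or with an embryo made in vitro and transferred to a recipient (ET) and that were ended on day 18 or day 25 of gestation. The comparison asks how the route by which a pregnancy began is reflected in the transcripts of the mother's and the embryo's side of the contact zone. The endometrium was sampled in its caruncular part, the gland-free knobs to which the placenta later attaches, and in its intercaruncular part, the glandular tissue between them. The conceptus was represented by extra-embryonic tissue on day 18 and by chorion, the outer fetal membrane, on day 25.

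The series held 215 libraries. On day 18 there were 21 AI and 23 ET libraries of caruncular endometrium, 21 and 24 of intercaruncular endometrium, and 10 and 8 of extra-embryonic tissue. On day 25 there were 21 AI and 21 ET libraries of each endometrial part, and 12 AI and 12 ET libraries of chorion. The libraries came from 29 gestation numbers, and the gestation, not the library, was the replicate. The endometrium of each part was available from 7 AI and 8 ET gestations on day 18 and from 7 AI and 6 ET gestations on day 25. The extra-embryonic tissue used came from 7 AI and 7 ET gestations, and the chorion from 6 AI and 6 ET gestations. ET gestation 162 on day 25 had 16 libraries, more than any other number, and whether all come from 1 animal is not known, so the ET count of 6 gestations on day 25 rests on its label.

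Depth differed between the treatments. The median library held 12.2 M counts (M stands for 1000000) in AI and 22.5 M in ET. In caruncular endometrium on day 25 the medians were 10.8 and 22.1 M, and in intercaruncular endometrium on day 25 they were 8.07 and 22.6 M. In extra-embryonic tissue the order was the other way, with 24.1 M in AI and 14.5 M in ET. Single libraries ranged from 2 counts to 33.1 M, and 10 of them held under 1 M. After the libraries of each gestation and tissue were added up, the sums used ranged from 1.74 M to 145 M. The files name genes only by Ensembl identifier and do not pair these with gene symbols, so identifiers are given for the extremes of a comparison and the other genes are described by the tissue in which they were high.

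The 2 parts of the endometrium differed in a large share of their genes. On day 18, 9278 of 18377 genes tested were called different (edgeR quasi-likelihood test with the gestation as a block, Benjamini-Hochberg adjusted), 4436 of them higher in caruncular and 4842 higher in intercaruncular endometrium. On day 25 the numbers were 9715 of 18434, with 5014 higher in caruncular and 4701 higher in intercaruncular tissue. At least 2-fold differences were found for 2281 genes on day 18, 1223 higher in caruncular and 1058 higher in intercaruncular tissue. On day 25 there were 2565 such genes, 1116 higher in caruncular and 1449 higher in intercaruncular tissue. The gene ENSBTAG00000005985 had 1.63 ± 1.78 CPM in intercaruncular and 59.9 ± 30.9 CPM in caruncular tissue on day 18 (SD, n = 15 each), a log2 fold change of 5.47 ± 0.28 (SE). On day 25 it had 2.78 ± 2.28 and 135 ± 63.0 CPM (n = 13 each), a log2 fold change of 5.76 ± 0.30. In the other direction, ENSBTAG00000017194 had 23.9 ± 19.7 CPM in intercaruncular and 3.27 ± 3.46 CPM in caruncular tissue on day 18. The days were studied in different animals. Among 18036 genes tested on both days, 3518 were called higher in caruncular tissue on both, 3577 were called lower on both, and 32 were called in opposite directions, where independent lists of these lengths would share 1203 higher and 1217 lower genes. Without the gestation block the day 18 count fell to 6026, and on day 25 it was 8621.

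Between day 18 and day 25 the endometrium changed in about as many genes in either part. In caruncular tissue 5857 of 18437 genes were called, 2687 higher and 3170 lower on day 25, and 1818 of these changed at least 2-fold. In intercaruncular tissue 6487 of 18569 genes were called, 3200 higher and 3287 lower, and 1924 changed at least 2-fold. Of the 18103 genes tested in both parts, 2049 rose in both, 2394 fell in both and 2 were called in opposite directions. Independent lists would share 461 and 561.1, but the parts come from the same gestations and are not independent. In caruncular tissue ENSBTAG00000025302 went from 0.0453 ± 0.118 CPM on day 18 (n = 15) to 24 ± 21.9 CPM on day 25 (n = 13), and ENSBTAG00000008394 from 48.8 ± 38.6 to 1.82 ± 0.899 CPM. In intercaruncular tissue ENSBTAG00000055080 went from 0.00851 ± 0.0178 to 158 ± 110 CPM, and ENSBTAG00000034674 from 23.3 ± 22.8 to 1.33 ± 1.25 CPM. These day effects are averages over AI and ET.

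In caruncular endometrium on day 25, ET pregnancies had lower levels than AI pregnancies of 1001 genes and higher levels of 251, together 1252 of 17654 genes tested. At least 2-fold changes were found for 452 lower and 64 higher genes. The most strongly lowered gene among those with a mean of at least 5 CPM, ENSBTAG00000055172, had 17.4 ± 27.4 CPM in AI (SD, n = 7) and 0.688 ± 0.678 CPM in ET (n = 6), a log2 fold change of -4.67 ± 1.09 (SE, edgeR adjusted p = 0.027). The most strongly raised, ENSBTAG00000031640, had 1.78 ± 1.69 CPM in AI and 12.1 ± 15.4 CPM in ET, a log2 fold change of 2.78 ± 0.76 (edgeR adjusted p = 0.0428). The ranges of the 2 treatments overlapped for both genes. Of 1177 tested genes that had been at least 2-fold higher in caruncular than in intercaruncular tissue on day 18 (caruncle-high), 36 rose and 19 fell in ET, with a median log2 fold change of 0.12 (camera adjusted p = 0.0353, adjusted p = 0.62 with an estimated correlation). Of 824 intercaruncle-high genes 3 rose and 24 fell, with a median of -0.08 (camera adjusted p = 0.74, adjusted p = 0.94 with an estimated correlation). Among 395 genes that were far higher in the conceptus than in endometrium on day 18 (conceptus-high), 8 rose and 22 fell, and among 1352 endometrium-high genes 48 rose and 71 fell (camera adjusted p = 0.739 for both).

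The number of caruncular genes called on day 25 depended on single gestations. No gene was called without ET gestation 107, 120 or 162, and 283 were called without ET gestation 104. Without ET gestation 10 or 28 there were 4621 or 1338. The count thus fell without any ET gestation numbered 100 or more, and rose without either numbered below 100. Leaving out AI gestation 39, 18, 44, 19 or 1 gave 263, 320, 570, 614 or 2051 genes. At least 1249 of the 1252 genes kept their direction in each of these fits. Where the calls ended the folds stayed about as large, with a median absolute log2 fold change of 0.84, 0.82 and 0.87 without gestation 107, 120 and 162, against 0.90 with all gestations. The genes were chosen with all gestations and each fit reuses all gestations but 1, so this is no independent support. No gene was called either when all groups of the region shared a fit (median 0.89) or when ET was limited to its 2 gestations with a number below 100, while DESeq2 called 2987 genes and limma on single libraries 6392. In limma the correlation between libraries of one gestation was set at 0.153 for all genes, so libraries counted nearly as separate replicates. The balance of directions depended on the fit too, with 1035 genes higher and 1952 lower in ET by DESeq2, 2042 and 2579 without ET gestation 10, and 3397 and 2995 by limma. By whole profiles, 11 of the 13 gestations lay nearer the mean of their own treatment than that of the other (exact permutation p = 0.0134, one-sided, adjusted p = 0.0402 over 6 tissues and days, a test chosen after the data were seen).

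Libraries of the same gestation and region also differed from each other, along an axis that was nearly the same on both days (r = 0.948 between the days over genes) and took 40.0% of that variation on day 18 and 44.2% on day 25. Gestations were scored on the axis of the other day, an approach chosen after the data were seen. The sign of the axis was set so that, within a gestation and part, scores rose with library depth. In caruncular tissue on day 25 the ET gestations lay 1.14 SD above the AI gestations (exact permutation p = 0.0355, two-sided, adjusted p = 0.142 over 4 tests), and the log2 fold changes of ET against AI followed the weights of the genes on the axis (r = 0.633 across genes), with 96.3% of the 1152 called genes that have a weight changing in its direction. In intercaruncular tissue on day 25 the difference was 0.953 SD (exact permutation p = 0.0857, adjusted p = 0.171), r was 0.501, and 77.8% of the 252 called genes with a weight changed in its direction. On day 18 the differences were 0.456 SD in caruncular and 0.419 SD in intercaruncular tissue (exact permutation p = 0.384 and 0.435). There r was 0.585 and 0.42, although no gene was called. The r values and shares were not set against permuted labels, so their size alone does not mark the day 25 effect.

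**Figure D1:**
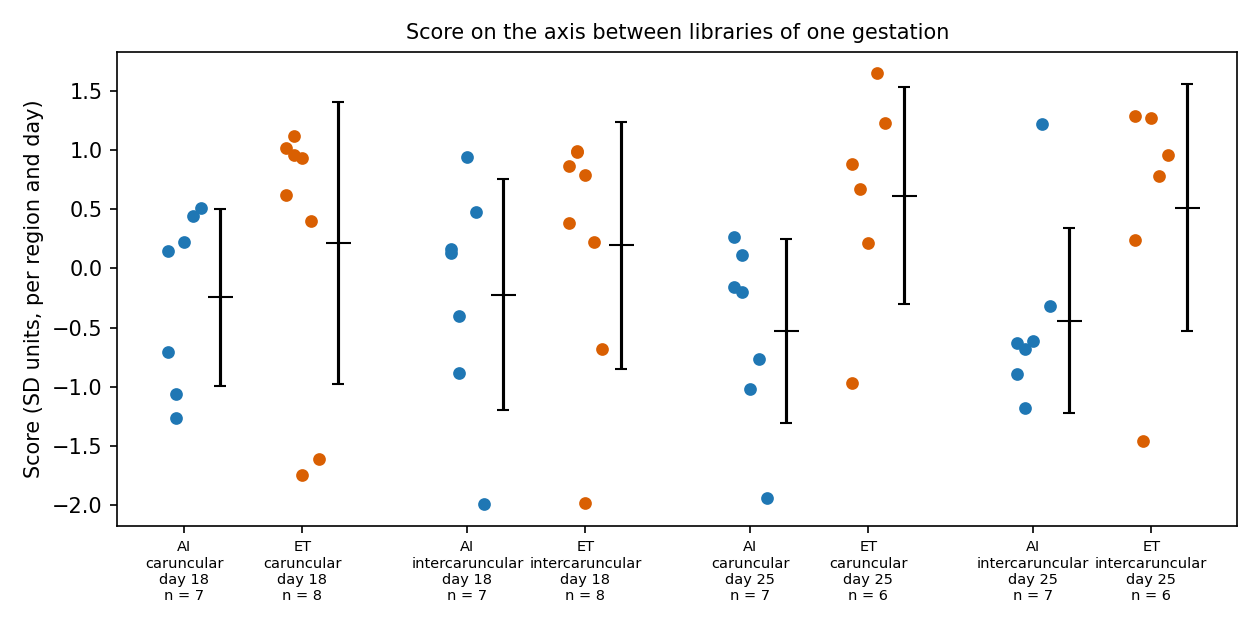
Score of each gestation on the axis of variation between libraries of one gestation, in SD units within each region and day, by treatment. Points are gestations, bars to their right give the mean and SD, and in caruncular tissue on day 25 the means are -0.527 in AI and 0.615 in ET.

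In intercaruncular endometrium on day 25, 285 of 17748 genes were called, 173 lower and 112 higher in ET. At least 2-fold changes were found for 105 lower and 48 higher genes. ENSBTAG00000015940 had 16.2 ± 14.6 CPM in AI (n = 7) and 0.93 ± 1.06 CPM in ET (n = 6), a log2 fold change of -4.20 ± 0.81 (SE, edgeR adjusted p = 0.0345), and ENSBTAG00000006732 had 1.30 ± 0.744 and 10.9 ± 7.36 CPM, a log2 fold change of 3.05 ± 0.53 (edgeR adjusted p = 0.0345). The group medians pointed up for genes typical of the glandular part and down for genes typical of the caruncles. Of 987 tested genes that had been intercaruncle-high on day 18, 27 rose and 3 fell, with a median log2 fold change of 0.33 (camera adjusted p = 1.25e-07, adjusted p = 0.67 with an estimated correlation). Of 1021 caruncle-high genes 1 rose and 37 fell, with a median of -0.19 (camera adjusted p = 0.000404, adjusted p = 0.67 with an estimated correlation). Among 407 conceptus-high genes 0 rose and 11 fell, and among 1352 endometrium-high genes 37 rose and 38 fell (camera adjusted p = 0.739 and 0.171). Whole profiles placed 11 of 13 gestations nearer their own treatment (exact permutation p = 0.0291, adjusted p = 0.0582).

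This count too depended on single gestations. No gene was called without AI gestation 3 or 18 or ET gestation 104, 107, 120 or 162. These ET gestations are the ones of day 25 numbered 100 or more. Without AI gestation 40, 39, 44 or 1 there were 4, 10, 15 or 150 genes, and without AI gestation 19 there were 2914. Without ET gestation 10 or 28, both numbered below 100, there were 201 or 4188. At least 279 of the 285 genes kept their direction in each of these fits. In the fits with no call the median absolute log2 fold change of these genes lay between 0.95 and 1.05, against 1.04 with all gestations. These genes too were chosen with all gestations, most of which each fit reuses, so kept directions and folds are no independent support. With the 2 ET gestations numbered below 100 no gene was called, a fit over all groups of the region called 150, DESeq2 called 1847, and limma on single libraries called 5023. In limma the correlation between libraries of one gestation was 0.12, so libraries counted nearly as separate replicates. The larger number was of lower genes by DESeq2 (705 higher, 1142 lower) and without ET gestation 28 (1750 and 2438), but of higher genes by limma (2770 and 2253) and without AI gestation 19 (1580 and 1334), 39 (8 and 2) or 44 (8 and 7).

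Over all genes the log2 fold changes of ET on day 25 in the 2 parts of the endometrium were correlated, while the genes typical of either part had medians of opposite sign in them. Caruncle-high genes had a median of 0.12 in caruncular and -0.19 in intercaruncular tissue, and intercaruncle-high genes -0.08 and 0.33, a difference between the parts that was not tested for these groups and whose 3 calls by camera within a part were lost with an estimated correlation (adjusted p = 0.62, 0.67 and 0.67). Of 17314 genes tested in both, 75 were lower in ET in both and 30 were higher in both, where independent lists would share 9.84 and 1.57, and 0 were called in opposite directions. Across genes the log2 fold changes of the parts correlated with r = 0.831. Genes are not independent replicates and the parts come from the same gestations, so r was set against 100 permutations of the treatment labels over gestations, which gave a median of 0.485 and reached the observed size in 1. The covariance was 0.22 against a permuted median of 0.035. On day 18 r was 0.746 against a permuted median of 0.51, and 16 of 100 permutations were as large. A test of whether the ET effect differed between the parts called 0 genes on day 25, with 1170 of 18434 at an unadjusted p below 0.05 in edgeR and 132 called by DESeq2, and 0 on day 18, with 679 of 18377 and 1 by DESeq2.

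On day 18 no gene was called in either part of the endometrium by edgeR. In caruncular tissue 996 of 17625 genes had an unadjusted p below 0.05, DESeq2 called 20, limma on single libraries called 4, and 14 were called by edgeR without ET gestation 31. That count of 996 became 2770 without ET gestation 31, 2141 without ET gestation 15, and 627, 631 and 622 without AI gestation 9 and ET gestations 115 and 169. In intercaruncular tissue 1305 of 17605 genes had an unadjusted p below 0.05, DESeq2 called 49 and limma called 16. The 1305 became 2646 without ET gestation 15, 836 and 851 without ET gestation 115 and 169, and 542 with ET gestations numbered below 100, against 399 with these in caruncular tissue. With simulated counts of the same depth and spread but independent genes, the test recovered 80% of 4-fold changes in caruncular tissue on day 18 and 78% in intercaruncular tissue. Of 2-fold changes it recovered 42% and 28%. Among gene groups defined on day 25, caruncle-high and intercaruncle-high genes had medians of 0.13 and 0.22 in caruncular tissue (camera adjusted p = 0.0249 and 0.0353, adjusted p = 0.67 and 0.922 with an estimated correlation). In intercaruncular tissue their medians were 0.13 and 0.20 (camera adjusted p = 0.0476 and 3e-04, adjusted p = 0.866 and 0.62 with an estimated correlation). Conceptus-high and endometrium-high genes had camera adjusted p values between 0.681 and 0.74 in both parts.

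Whether the ET effect changed with the day was tested directly. In intercaruncular endometrium 6 of 18569 genes had an interaction of treatment and day, 3 in each direction. ENSBTAG00000034323 was lower in ET on day 18 (log2 fold change -2.81 ± 0.60, SE) and higher on day 25 (2.31 ± 0.58), ENSBTAG00000007302 went from -2.79 ± 0.56 to 1.38 ± 0.45, and ENSBTAG00000007534 from -1.06 ± 0.24 to 0.61 ± 0.19. In the opposite sense, ENSBTAG00000034402 went from 0.86 ± 0.27 to -1.58 ± 0.32, ENSBTAG00000019081 from 0.48 ± 0.17 to -1.02 ± 0.18, and ENSBTAG00000021466 from 0.52 ± 0.19 to -0.77 ± 0.15. The edgeR adjusted p of the interaction lay between 0.0272 and 0.0496 for these 6 genes, which are all named whatever their level, a choice made after their values were seen, and DESeq2 called 124 genes. In caruncular endometrium edgeR called 0 of 18437 genes, with 1124 at an unadjusted p below 0.05, and DESeq2 called 30. Of the caruncular genes called on day 25, 1233 were also tested on day 18, and 1069 of them, 86.7%, had the same direction there, with a median log2 change of 0.30 in that direction on day 18 against 0.89 on day 25. In intercaruncular tissue 191 of 277 did, 69%, with medians of 0.15 and 1.03. The fold changes of the days correlated across genes with r = 0.479 in caruncular and 0.443 in intercaruncular tissue. An r of that size in either direction came from 12 and 5 of 100 label permutations. The covariances of 0.0951 and 0.101, counted in the positive direction only, were reached by 2 and 0 of 100 permutations. With genes of at least 5 CPM, 15 and 20 of 100 reached the r and 1 and 3 the covariance, counted in the same ways. The lower counts for the covariance are therefore partly due to leaving out the negative side. These comparisons of the days were added after the data were seen.

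The day 18 extra-embryonic tissue separated by treatment as a whole more clearly than by single genes. By edgeR 0 of 14089 genes were called, the smallest adjusted p being 0.0641, while 3397 genes, 24.1%, had an unadjusted p below 0.05. DESeq2 called 1320 and limma on single libraries 1142. In whole profiles of 10180 genes, 13 of 14 conceptuses lay nearer the mean of their own treatment (exact permutation p = 0.00524, one-sided, adjusted p = 0.0314, chosen after the data were seen). The exception was the ET conceptus of gestation 31, at a distance of 0.455 from the AI mean and 1.04 from the ET mean in root mean square log2 CPM. Without gestation 31 edgeR called 3343 genes, 1578 higher and 1765 lower in ET, and 5265 had an unadjusted p below 0.05. Without ET gestation 33 it called 70, and with ET gestations numbered below 100 it called 0, with 1885 at an unadjusted p below 0.05. All 4 gene groups defined on day 25 had medians below 0 in ET. The median log2 fold change was -0.54 over 371 caruncle-high genes, -0.45 over 413 conceptus-high genes, -0.47 over 244 endometrium-high genes and -0.16 over 773 intercaruncle-high genes. Their camera adjusted p values were 1.25e-07, 8.24e-06, 3e-04 and 0.0512, and the adjusted p = 0.62 with an estimated correlation for each of the 4.

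**Figure D2:**
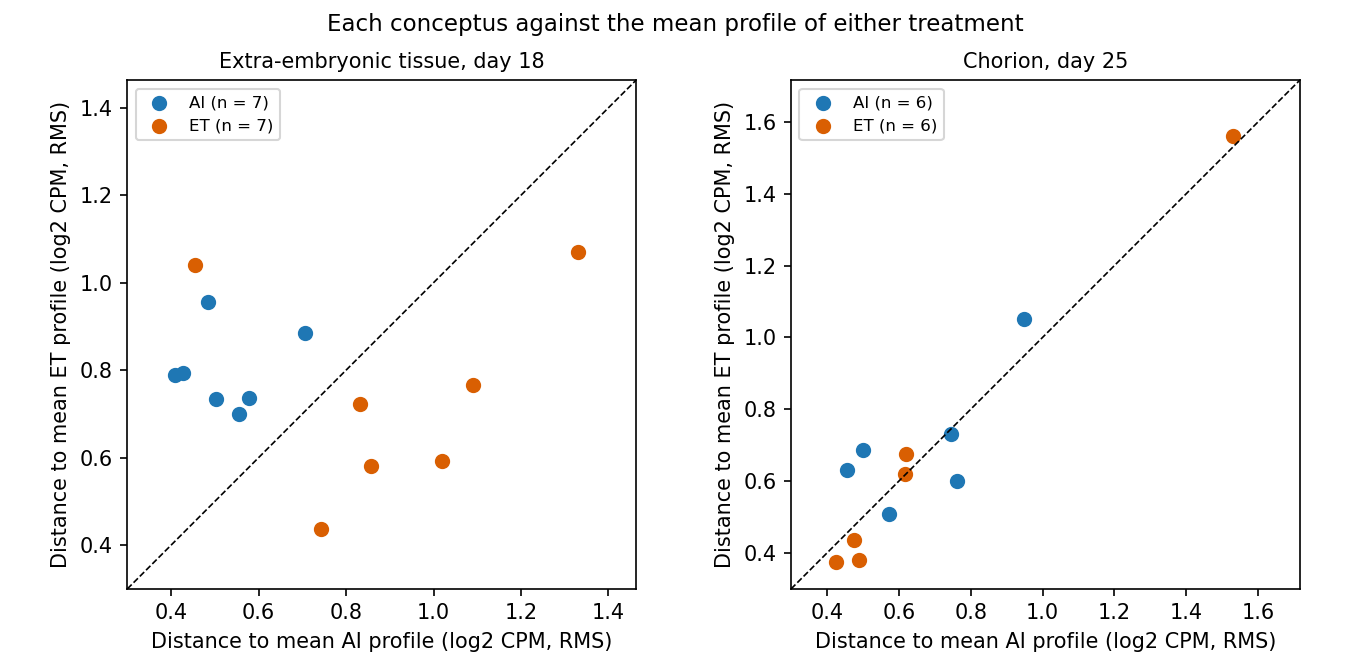
Distance of each conceptus to the mean AI profile (horizontal) and to the mean ET profile (vertical), in root mean square log2 CPM over genes with a mean of at least 5 CPM, the conceptus itself being left out of its own group's mean. Points are conceptuses, the dashed line marks equal distance, and 13 of 14 day 18 conceptuses but 6 of 12 day 25 chorions lie on the side of their own treatment.

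In the chorion on day 25 no gene was called by edgeR among 16526 tested, and 1423 had an unadjusted p below 0.05, or 2619 without ET gestation 10. DESeq2 called 182 genes and limma on single libraries 158, the latter with a correlation of -0.109 between libraries of one gestation. Whole profiles placed 6 of 12 chorions nearer their own treatment (exact permutation p = 0.511, adjusted p = 0.511). In simulated counts of the same depth and spread but with independent genes, the test recovered 74% of 4-fold and 14% of 2-fold changes. Most 2-fold changes were missed there, so the lack of calls does not exclude such changes. Conceptus-high genes of day 18 had a median log2 fold change of 0.17 (camera adjusted p = 0.0249, adjusted p = 0.67 with an estimated correlation), and the other 3 groups had medians between 0.03 and 0.10 (camera adjusted p from 0.0541 to 0.74). The ET effects of extra-embryonic tissue on day 18 and chorion on day 25 correlated across genes with r = 0.0346, a comparison also added after the data were seen. An r of that size in either direction came from 85 of 100 label permutations. The covariance of 0.0123, counted in the positive direction only, was reached by 35 of 100.

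Genes that were conceptus-only on the other day, in other animals, were summed in the endometrium. Only 13 genes were conceptus-only on both days, and expression of the others by the endometrium itself was not set aside, so the sums do not measure RNA of the conceptus alone. The 46 genes that had at least 50 CPM in extra-embryonic tissue and under 1 CPM in either endometrial part on day 18 summed on day 25 to a median of 41.3 CPM in AI and 61.2 CPM in ET caruncular tissue (exact permutation p = 0.0728, two-sided, adjusted p = 0.145 over 6 tests), and to 43.3 and 92.3 CPM in intercaruncular tissue (exact permutation p = 0.0484, adjusted p = 0.145). In the chorion they summed to 6556 CPM. On day 18, where 48 genes defined on day 25 were summed, the medians were 5.60 and 6.92 CPM in caruncular tissue (exact permutation p = 0.0965) and 5.35 and 6.43 CPM in intercaruncular tissue (exact permutation p = 0.265). In the reverse direction, 44 genes that were endometrium-only on day 25, 30 of them also on day 18, summed to 6.37 CPM in AI and 3.39 CPM in ET extra-embryonic tissue (exact permutation p = 0.00291, adjusted p = 0.0175). These sums are near the floor: the highest was 0.17% of the median of 5268 CPM in caruncular endometrium on day 18. In the chorion 209 genes that were endometrium-only on day 18, of which the same 30 were so on day 25, summed to 1910 and 2050 CPM (exact permutation p = 0.983).

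**Figure D3:**
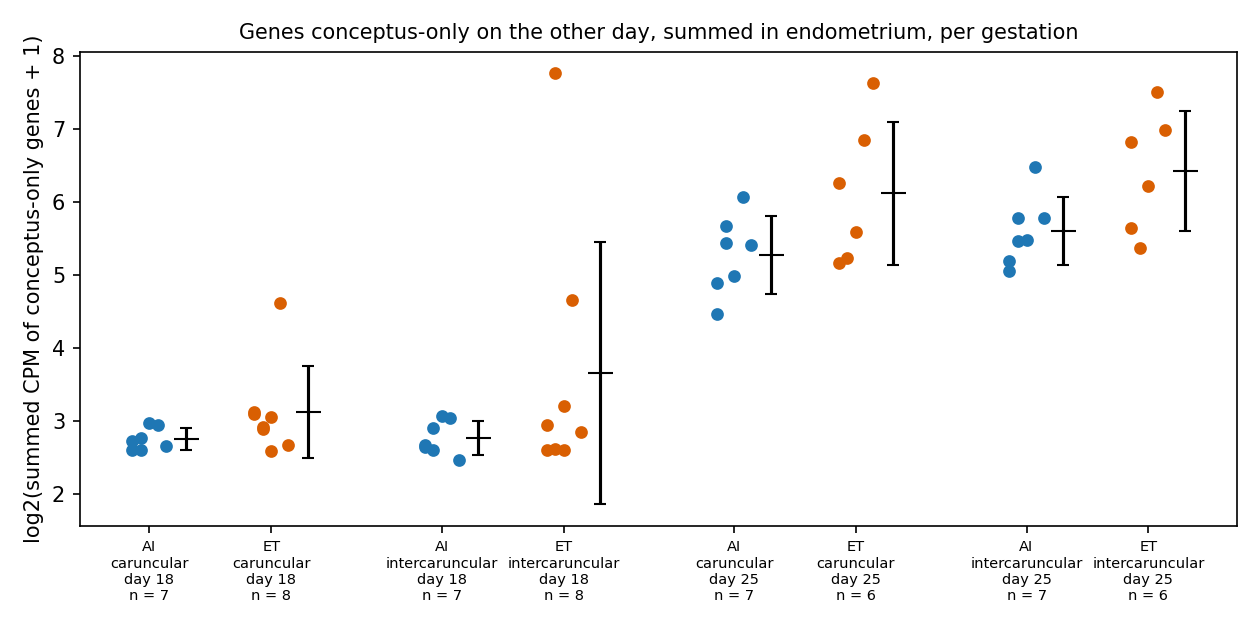
Summed CPM in endometrium of genes that were conceptus-only on the other day, as log2(CPM + 1), for each gestation by part, day and treatment. Points are gestations, bars to their right give the mean and SD, and the day 25 means are 5.27 in AI and 6.12 in ET caruncular tissue, and 5.60 and 6.42 in intercaruncular tissue. The genes summed differ between the days, so levels are comparable within a day only.

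Pairs of a conceptus gene and an endometrial gene that varied together across the gestations of a treatment were counted among the 1000 most variable genes of each tissue, with an absolute Pearson r of at least 0.9. With extra-embryonic tissue and caruncular endometrium there were 4452 pairs in AI and 3691 in ET, and with intercaruncular endometrium 10360 and 8074. With chorion on day 25 there were 18001 and 31753 pairs for caruncular, and 10016 and 20687 for intercaruncular endometrium. None of these 8 counts exceeded what random pairing of gestations gave, since between 11 and 96 of 100 re-pairings gave as many. The differences between AI and ET were matched by 91, 80, 32 and 32 of 100 permutations of the treatment labels.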

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

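In this part, the tests by axis position in other splits, and the other splits for the interaction and the day effect in intercaruncular tissue and for the comparison of the 2 parts, were set down before their results were seen, and the depth, number, label and remaining split tests were chosen after.

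The ET effect on day 25 in caruncular endometrium (1252 genes) exceeded every other split tried. Of 100 splits of the gestations only the real one gave as many, and the highest other gave 43. That is the lowest share 100 splits can give and was not adjusted over the comparisons, so it speaks against chance without excluding it. With all sums thinned to the smallest, 1274 genes were called, which argues against counting precision, and 7 other splits with at least 80% of the real difference on the axis between libraries called at most 43, which argues against position on the axis as the whole source. The axis may still account for part of the effect: with the score as a covariate no gene was called, the median absolute log2 fold change of the 1252 genes fell from 0.90 (median SE 0.21) to 0.50 (0.17), and all 1252 kept their sign. Whether the ET gestations numbered 100 or more are a batch of their own cannot be told apart from the treatment, because with only 2 ET gestations numbered below 100 the median was 0.53 (SE 0.29). An effect of the transfer and in vitro production stays open beside whatever made the ET libraries deeper. The sums ran from 23.15 to 46.52 M counts in AI and from 57.45 to 128.8 M in ET, without overlap. Log10 of the sum as a covariate therefore nearly repeats the treatment. Its 0 calls, with a median of 0.55 (SE 0.34), cannot tell depth and treatment apart.

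The ET effect on day 25 in intercaruncular endometrium (285 genes) was equalled or passed by 2 of 100 splits, the real one included. The share is low but was not adjusted over the comparisons, and a split other than by treatment passed the real count, so chance is not excluded. The highest other split called 4896 genes, many times the real count, which points to a structure of the samples. That split had a difference of 1.52 SD on the axis between libraries, and the most genes among the 12 other splits with at least 80% of the real difference were also 4896, so position on the axis is a candidate source of this effect. Thinning to the smallest sum left 241 genes, which argues against counting precision, and the score as a covariate left 0, with the median absolute log2 fold change going from 1.04 (SE 0.21) to 0.80 (0.22). Gestation number stays open for want of gestations (median 0.76, SE 0.30, with the 2 ET gestations numbered below 100), as does an effect of the treatment itself.

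The day 18 conceptus of gestation 31, labelled ET, lay nearer the AI conceptuses, and 97.2% of the 3331 genes called without it and tested with it had a level nearer AI in it. Its sum of 27.4 M counts against an ET median of 22.7 M argues against low depth. An exchange of labels with an AI conceptus would need a partner, and 0 AI conceptuses lay nearer the ET mean. A single wrong label and an ET conceptus that resembles AI conceptuses cannot be told apart, since its distance of 0.455 to the AI mean is within the AI conceptuses' own distances of up to 0.706. No biological explanation beyond the treatment was tested.

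Of 36 sets of values, each 1 measure in 1 group of samples, 6 had a value far from the others, where chance gives about 5%. The measures reuse the same gestations, so the 36 sets are not independent. The summed counts of ET gestation 162 on day 25 were 129 M in caruncular tissue (next 74.3 M) and 145 M in intercaruncular tissue (next 69.8 M). It had 6 libraries of each part, where the other ET gestations of that day had 3. AI gestation 19 had an axis score of 1.22 in intercaruncular tissue on day 25, and the next AI gestation had -0.313. The sum of genes that were conceptus-only on day 25 was on day 18, as log2(CPM + 1), 4.61 in caruncular tissue of ET gestation 27 (next 3.12) and 7.76 in intercaruncular tissue of ET gestation 115 (next 4.66). In gestation 115 it came to 600 CPM in 1 library and to 4.4 and 5.72 CPM in its other libraries. The chorion of ET gestation 10 lay 1.56 from the mean of its treatment, in root mean square log2 CPM, and the next ET chorion 0.675. Apart from single samples, the ET effect differed between the days for 6 genes of intercaruncular tissue, by the interaction test.

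For that interaction 1 of 30 splits, the real one, gave 6 genes or more and the highest other gave 0. This is the lowest share 30 splits can give, and a split of the caruncular interaction gave 2230, so chance is not excluded for 6 genes. The day effect came to 5857 genes in caruncular tissue (1 of 30 splits, highest other 1) and 6487 in intercaruncular tissue (1 of 30, highest other 0). The comparison of the parts came to 9278 genes on day 18 (1 of 30, highest other 4243) and 9715 on day 25 (1 of 30, highest other 4517). For the day effect and the parts, real counts so far above the other splits speak against chance. Where the real count was 0 every split gives as many, so this count of splits decides nothing. On day 18 that holds for 100 of 100 splits in caruncular tissue (highest other 1), in intercaruncular tissue (8489) and in extra-embryonic tissue (2958), and on day 25 for 100 of 100 in chorion (2). For extra-embryonic tissue the whole-profile test does speak against chance, with 13 of 14 conceptuses nearer their own treatment (exact permutation p = 0.00524, adjusted p = 0.0314). It also holds for 30 of 30 splits of the caruncular interaction with day (2230) and of the interaction with region on day 18 (1) and day 25 (2). The split of intercaruncular gestations on day 18 that called 8489 genes had a difference of 1.51 SD on the axis, and such splits, like those with 2958 and 2230 genes, point to a structure of the samples.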

How the results depend on the processing

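The fits without shallow libraries, with thinned sums, with a covariate or without the library high in conceptus-only genes, and the gene groups, whole profiles, axis and agreement other than between the 2 parts, were chosen after the data were seen; the other alternatives were fixed before. Of 168 alternative counts of called genes, 113 lay within 1.5 times the reported count and 55 did not. A count of 0 against a reported 0 was also taken as within it, so the 113 include comparisons that called nothing. For the ET effect on day 25, of 13 fits with 1 gestation left out, 3 in caruncular and 1 in intercaruncular tissue lay within 1.5 times the reported count. RLE size factors kept all 14 counts within it, with 19.6% of the calls higher in caruncular tissue on day 25 against 20%, but this balance moved with the tool and the gestations used (3397 higher and 2995 lower by limma, against 251 and 1001). Without a low-count filter 13 of 14 did, the exception being the interaction with region on day 25 (1 gene), and without libraries under 1 M counts all 6 did. DESeq2 called more genes in all 14 comparisons, by over 1.5 times in 10. For ET against AI it called 20 genes in caruncular, 49 in intercaruncular and 1320 in extra-embryonic tissue on day 18, and 2987, 1847 and 182 in caruncular, intercaruncular and chorion tissue on day 25. Interactions with day came to 30 (caruncular) and 124 (intercaruncular), and with region to 1 (day 18) and 132 (day 25). With limma on single libraries the 6 counts, in the same order, were 4, 16, 1142, 6392, 5023 and 158. The correlations it used between libraries of one gestation were 0.532, 0.426, 0.594, 0.153, 0.12 and -0.109. On day 25 libraries thus counted nearly as separate replicates. In caruncular and intercaruncular tissue on day 25 there were 0 calls each with ET gestations numbered below 100, without gestation 162, with the axis score and with log10 of the sum as a covariate. With the last the median absolute log2 fold change was 0.55 (SE 0.34) and 0.90 (0.27), against 0.90 and 1.04. In caruncular tissue the sums of AI and ET did not overlap, so this covariate could not separate depth from treatment. The fit over all groups gave 0 and 150, with a median SE of 0.35 and 0.27 against 0.21 for both. Thinning gave 48 genes in extra-embryonic tissue. The 2 parts differed in 6026 genes on day 18 without the gestation block. Leaving out 1 gestation at a time gave, on day 18, 0 to 14 genes in caruncular tissue (14 without ET gestation 31), 0 to 1 in intercaruncular (without ET gestation 33) and 0 to 3343 in extra-embryonic tissue (without 31). On day 25 it gave 0 to 4621 in caruncular tissue (without ET gestation 10), 0 to 4188 in intercaruncular (without ET gestation 28) and 0 in chorion. The cause was not tested for any of these changes, except that fewer gestations were used where some were left out. Of 24 tests of gene groups camera called 11 with a preset correlation, 0 with an estimated one, and fry called 0. The 8 co-expression counts, 5 agreement values (by r) and 6 whole-profile tests stayed on their side of the threshold. Depth and treatment went together on day 25 (medians of 10.8 M in AI and 22.1 M in ET in caruncular tissue), so an effect of what made the ET libraries deeper is not separated from the treatment. Not run, for want of gene symbols, were the named gene lists, the relation of interferon tau with its alternatives, the XIST covariate and the genes named by symbol.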

Other observations

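All tests in this part were chosen after the data were seen. Endometrial libraries resembled other libraries of the same gestation and part more than those of other gestations, and more so on day 18. On day 18 the mean Pearson r of profiles was 0.449 within and -0.0725 between gestations in intercaruncular tissue, and 0.446 and -0.071 in caruncular tissue (permutation p = 1e-04 for both, one-sided, the smallest the permutations can give). On day 25 it was 0.171 and -0.0655 in intercaruncular tissue (permutation p = 1e-04) and 0.154 and -0.0743 in caruncular tissue (permutation p = 0.0016). In the chorion 14 pairs of libraries with the same gestation number had a mean r of -0.285, below the -0.0465 of other pairs. The test was for a higher r within gestations (permutation p = 0.961, one-sided), so the lower value was not tested. In extra-embryonic tissue only 3 pairs shared a gestation (0.148 against -0.131, permutation p = 0.122). The difference between the days was not tested. On day 25, ET gestation 162 had 6 libraries of each endometrial part and 4 of chorion, and so gave many of the pairs there. Whether all of them come from 1 animal is not known.

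The axis between libraries of one gestation was compared with other traits as deviations from the mean of each gestation and part. Its r was 0.771 on day 18 and 0.84 on day 25 with the number of genes above 1 CPM. With log10 of the library's total r was 0.231 and 0.265, positive because the sign of the axis was set by it. These are descriptions over libraries that share gestations, so no p is given.

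A hypothesis was that ET pregnancies may lag behind AI pregnancies in the changes from day 18 to day 25, in which case the ET effect on day 25 would run against the day effect over genes. With the AI gestations divided so that the effects shared no control, r was -0.173 in caruncular and -0.129 in intercaruncular tissue, and 8 and 17 of 100 label permutations gave an r as low, or 20 and 39 an r of that size in either direction. With shared controls r was -0.296 and -0.241, where the shared AI gestations alone can give a negative value. The data leave the hypothesis undecided.

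The lowest library totals were 2 counts (chorion, AI gestation 40), 18 (intercaruncular, ET gestation 28), 61 (extra-embryonic, ET gestation 8), 1896 (intercaruncular, ET gestation 15), 28294 (caruncular, AI gestation 19) and 42024 (caruncular, AI gestation 5).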
